A study of Mus musculus with 12 samples.

How the data were processed

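Liver RNA from 12 male mice was measured on one-colour (Cy3) Agilent mouse expression arrays, 1 array per mouse. The mice were wild type or lacked Akp3, the gene for an intestinal alkaline phosphatase (IAP), an enzyme of the gut brush border. Per the labels they were 7 weeks old and received either vehicle (5 g/L carboxymethylcellulose) or 600 mg/kg per day of IIAEK by mouth, once a day for 14 days, and were fasted for 8 h before the liver was taken. IIAEK is a peptide with the residues Ile-Ile-Ala-Glu-Lys. One label field of the IIAEK samples gives weeks where the sample titles and the series description give days, and 14 days was used. Each of the 4 groups held 3 mice. Replicate 1 of every group was on slide 1 (4 arrays) and replicates 2 and 3 on slide 2 (8 arrays), and each slide had a scan day of its own, so slide and scan day cannot be separated.

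Per the file headers, each array was read with Agilent Feature Extraction 10.7.3.1, and the processed signal is an intensity per spot from which the software had subtracted the background, without scaling between arrays. The deposited files also hold the median intensity of each spot and of its local background, and the software's flags for spots well above background, saturated spots and non-uniform spots. The deposited series table holds log2 values. When tested against the scanner files, its columns matched log2 signals shifted to the array's 75th percentile and then centred on each probe's median over the 12 arrays (Pearson r across probes 0.9997 to 0.9999). Its column medians were 0.171, -0.0389 and -0.154 for wild-type vehicle, 0.154, 0.0668 and 0.0707 for wild-type IIAEK, -0.127, -0.0513 and -0.110 for knockout vehicle, and 0.0145, -0.0485 and 0.0527 for knockout IIAEK.

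Each array gave 62976 spots, of which 59305 were not controls, and 0 spots were saturated. Spots marked as non-uniform were left out and the signals of the remaining spots of a probe were averaged before log2 was taken, which gave 56605 probes. The files name probes by transcript and not by gene. Names were taken from a table of mouse RefSeq transcripts, which named 32994 probes (22911 symbols). All 7284 probes for Ensembl transcripts stayed without a symbol and were tested under their own names. The file headers give the build mm9 and the table of names another build (GRCm38.p6), so the table was used only for names and for the order of genes along a chromosome. A gene with several probes was represented by its brightest one.

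Values are log2 of the processed signal minus the array's 75th percentile on that scale. A gene was tested where its probe was well above background on all arrays of at least 1 group, which left 26399 genes. The linear models were fitted with limma 3.58.1 in R 4.3.3 to all 12 arrays with 1 mean per group, which leaves 8 residual degrees of freedom (prior degrees of freedom 2.70), and adjusted p is Benjamini-Hochberg over the 26399 genes, two-sided, with a threshold of 0.05. The 6 comparisons were the IIAEK effect in each genotype, the genotype effect in vehicle mice, the difference between both IIAEK effects (interaction), and the IIAEK and genotype effects averaged over the other factor. The fold of a gene below background in a whole group is given as a lower bound ("at least"), computed against the lowest signal above background. Errors beside group means are SD, and errors beside log2 changes are SE from limma.

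The design, the alternatives, the rule for named genes and 34 gene lists (metabolic and stress pathways, and markers of liver cell types, blood cells and neighbouring organs) were fixed before the data were examined. Lists with at least 5 tested members (33 of 34) were tested with camera of limma, which compares a list with all other genes, at its preset correlation of 0.01, and again with a correlation estimated per list and with fry, which tests whether the members move one way. The list of alkaline phosphatases had 1 tested member and was not tested as a set. Members called are also given adjusted over the list alone. Named genes were those past the threshold (up to 12 per direction). Where fewer than 4 passed in a direction, the genes with the smallest unadjusted p were added up to 4, given as not passing. Up to 4 called members, or otherwise the 2 with the smallest p, were named for each list described, as were Akp3, Alpi, Alppl2, Alpl and genes of cholesterol and bile acid metabolism. A few genes that this rule names are not reported here, and no others took their place. Which lists to describe was chosen after the list results had been seen.

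The alternatives were normexp background correction (offset 50, on median signals, since the deposited files hold no mean signals), quantile normalization, the series table, no filter, a filter on all 12 arrays, the mean over a gene's probes, the slide as a block, slide 2 alone, the replicate number as a block, only the groups compared, limma's trend and robust options, array weights, and leaving out each array. After the data had been seen, 5 were added, which left out 2 wild-type vehicle arrays with pancreas or intestine transcripts, left out 4 vehicle arrays that stood apart, permuted per-array list means exactly, dropped the interaction from the model, and took the whole chromosome of Akp3 as its neighbourhood. The pipeline was tested on simulated data by adding changes to 200 of the 26399 genes in the wild-type comparison. It recovered 38.8% of the genes changed 2-fold, 83.6% of those changed 4-fold and 92.4% of those changed 8-fold, with 5 false calls, and the list that had been shifted was among 2 lists called by camera. The simulated genes varied independently, without the correlation between genes that real arrays have. Recovery and false calls of genes and lists may therefore differ on the real arrays. The number of arrays limits the precision. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots.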

Results

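Expression was measured in the livers of 12 male mice, 3 in each of 4 groups: wild type given vehicle, wild type given IIAEK, Akp3 knockout given vehicle and Akp3 knockout given IIAEK. Akp3 encodes IAP, an alkaline phosphatase of the intestine. The 2 × 2 layout asks what IIAEK does to the liver, what the loss of Akp3 does, and whether the response to IIAEK depends on Akp3. The 75th percentile of the processed signal ran from 453.6 to 758.5 over the arrays, and 58.7% to 63.6% of the probes were well above background. The number of arrays limits the precision of every value.

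The 12 arrays did not fall into the 4 groups. The first principal component carried 55.3% of the variance, and it set 4 vehicle arrays (wild type 2 and 3, knockout 1 and 3, at 74.2 to 88.2) apart from the other 8 arrays (-57.3 to -11.3), which included wild-type vehicle 1 and knockout vehicle 2. These 4 arrays lay on both slides. Of the 2 remaining vehicle arrays, wild-type vehicle 1 had pancreas transcripts at a median log2 level of 2.72 above the 12-array mean. Small intestine transcripts stood at a median of 2.60 in wild-type vehicle 2, and less far up in wild-type vehicle 1 (0.90, with Sis at least 2.72) and wild-type vehicle 3 (0.47, with Muc2 at least 1.13). Some pancreas transcripts were also higher in wild-type IIAEK 1 (Try5 at least 2.29). Within groups, the median correlation between arrays was lowest for wild-type vehicle 1 (r = 0.953 across genes, which are not independent replicates) and highest in knockout IIAEK (0.993).

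**Figure D1:**
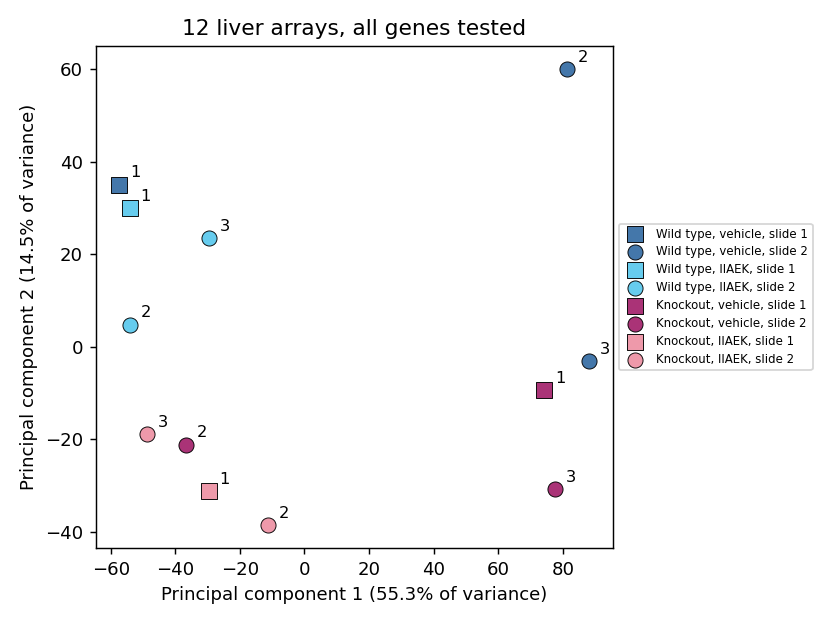
The 12 arrays on the first principal component (55.3% of the variance, horizontal) and the second (14.5%, vertical), with squares for slide 1, circles for slide 2 and numbers for the replicates. Wild-type vehicle 2 and 3 and knockout vehicle 1 and 3 lie at 74.2 to 88.2 on the horizontal axis and the other 8 arrays at -57.3 to -11.3.

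The targeted gene could not be read in this tissue. Both Akp3 probes and the Alppl2 probe were above background on 0 of 12 arrays and the Alpi probe on 1 of 12 (wild-type vehicle 2, the array with intestinal transcripts), so these genes say nothing about the genotype labels. Alpl, the tissue-nonspecific alkaline phosphatase of the liver, was above background on 12 of 12 arrays. Its log2 change with IIAEK was -0.54 (SE 0.28, n = 3 and 3) in wild type and -1.0 (SE 0.28) in knockout, and neither passed in limma (adjusted p = 0.411 and 0.656). On slide 1 the wild-type change was 0.08 and on slide 2 it was -0.85. Without the 4 vehicle arrays that stood apart, which leaves 1 vehicle array per genotype in this and every such setting below, it was 0.08. Those 4 lie farthest from the IIAEK arrays on the first component, so leaving them out shrinks IIAEK changes whatever their cause. A call of an IIAEK effect lost in that setting therefore does not decide whether IIAEK acts.

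The IIAEK effect in wild-type liver addresses what the peptide does where IAP is present. Transgelin (Tagln), an actin-binding protein of smooth muscle and contractile fibroblasts, fell from a log2 level of 3.48 ± 0.09 to 2.05 ± 0.20 (SD, n = 3 each), a 2.69-fold lower signal (log2 change -1.43, SE 0.15, limma adjusted p = 0.0318). It was lower in 3 of 3 IIAEK mice than in any of the vehicle mice. The call was lost with the slide as a block (adjusted p = 0.0705) and on slide 2 alone (0.111), and adjusted p for Tagln ran from 0.00426 to 0.530 over the alternatives. Genes with higher values that did not pass were Rgs3, a regulator of G-protein signalling (log2 change 1.27, SE 0.17), Gadd45g, a stress-induced growth arrest gene (1.32, SE 0.23), and the carboxylesterases Ces1g (0.93, SE 0.19) and Ces2a (1.79, SE 0.37), with adjusted p = 0.15 for Rgs3 and 0.394 for the others. The 4 probes of Rgs3 gave changes from 0.37 to 1.38. Lower values that did not pass were those of Gja1, the gap junction gene connexin 43 (-1.14, SE 0.23), Mrgpra4 (at least 2.25-fold lower, above background on 0 of 3 IIAEK arrays) and Hspa1l (at least 1.02-fold lower).

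Matrix, inflammation and early response genes fell as sets in wild type, of which only the early response call held without the 4 vehicle arrays that stood apart (adjusted p = 0.0153). In that setting the calls of matrix (0.894), macrophage (0.382) and NF-kappaB genes (0.0514) were lost. The fibrosis and extracellular matrix list had a median log2 change of -1.24 with 25 of 26 members lower, 1 of them (Tagln) called over all genes and 1 adjusted over the list alone (camera adjusted p = 6.33e-11, and adjusted p = 0.578 with an estimated correlation). In the endotoxin and NF-kappaB list, 24 of 27 members were lower with a median of -0.99 and 0 were called adjusted over the list alone (15 had an unadjusted p under 0.05; adjusted p = 5.78e-09, and 0.578 with an estimated correlation). Its members Irak3, a brake on Toll-like receptor signalling, and Tlr2, a receptor for bacterial lipoproteins, had changes of -1.49 (SE 0.44) and -1.82 (SE 0.55). Immediate early genes, the first transcripts to respond to growth and stress signals, had a median of -1.03, and adjusted over the list alone 10 of 23 were lower and 1 (Gadd45g) higher (adjusted p = 5.47e-06, and 0.578 with an estimated correlation). Egr1, a transcription factor of this list, stood at -2.43 (SE 0.63). Macrophage markers had a median of -0.69 with 16 of 19 lower, among them Marco at -2.74 (SE 0.87) and Ccr2 at -1.89 (SE 0.78), with 0 called adjusted over the list alone and 3 at an unadjusted p under 0.05 (adjusted p = 0.00147, and 0.705 with an estimated correlation). Its adjusted p ran from 2.84e-06 to 0.052 over the 12 left-out arrays and was lost without wild-type IIAEK 1.

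Metabolic genes rose as sets in wild type. The calls of PPARalpha targets (adjusted p = 0.926), fatty acid synthesis (0.260) and cholesterol synthesis (0.149) were lost without the 4 vehicle arrays that stood apart, where that of CAR and PXR genes stayed and male-biased genes were called in the opposite direction. All 22 tested genes of fatty acid and triglyceride synthesis were higher (median log2 change 0.78, adjusted p = 3.1e-06), with Pnpla3, a lipase of lipid droplets, at 1.52 (SE 0.41) and Acacb, which makes malonyl-CoA at mitochondria, at 2.22 (SE 0.76). The other probe of Pnpla3 gave -0.14 and that of Acacb 0.03. Of the PPARalpha targets and fatty acid oxidation genes, 26 of 31 were higher (median 0.55, adjusted p = 2.28e-05), with Vnn1, a pantetheinase, at 1.81 (SE 0.46) and the thioesterase Acot1 at 1.37 (SE 0.54). Acot1 stood at -0.57 on slide 1 and 2.34 on slide 2, and at 0.81 without wild-type vehicle 2. Cholesterol synthesis and SREBP2 targets were higher for 19 of 24 (median 0.55, adjusted p = 0.00107), with Hmgcs1, an early enzyme of the pathway, at 1.60 (SE 0.45) and Insig1, a sterol sensor of the endoplasmic reticulum, at 1.06 (SE 0.31). In these 3 lists 0 members were called adjusted over the list alone and 6 members each had an unadjusted p under 0.05. In the CAR and PXR list of drug-metabolizing genes 18 of 24 were higher (median 0.65, adjusted p = 0.00166), and 3 were called adjusted over the list alone, including Ces2a and Cyp3a11 (1.03, SE 0.25), the main PXR-induced P450 enzyme. All 4 lists lost their call with an estimated correlation (adjusted p = 0.578). Male-biased liver genes, which follow the pulses of growth hormone in males, had a median of 1.0 with 23 of 25 higher, including Keg1 at 1.95 (SE 0.96) and Ugt2b38 at 0.98 (SE 0.41), with 0 called adjusted over the list alone and 1 at an unadjusted p under 0.05 (adjusted p = 0.00173, and 0.737 with an estimated correlation). That call was lost without wild-type vehicle 2 or 3, with adjusted p from 2.35e-06 to 0.119 over the left-out arrays.

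Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass over all genes in wild type (adjusted p = 0.394). Its fitted log2 change was -5.09 (SE 1.27, unadjusted p = 0.00213 in limma), and as 1 of 3 IIAEK arrays was above background, the size of this change was not measured. Abca1, a cholesterol exporter, stood at -0.63 (SE 0.21) and Cyp8b1, Abcg5 and Abcg8 lay between -0.23 (Cyp8b1, SE 1.97) and 0.34 (Abcg8), with -0.11 for Abcg5. Npc1l1 was not tested, as it was too dim. The bile acid list as a whole was not called (median 0.25, adjusted p = 0.164), and Nr1h4, the bile acid receptor FXR, stood at 0.73. Cyp8b1 was above background on 1 of 3 arrays in each wild-type group and turned to 2.79 on slide 2. On slide 1 and slide 2 the changes were 0.08 and -0.21 for Abcg5 and -0.47 and 0.75 for Abcg8.

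Both the wild-type gene call and the list calls moved with single arrays and with the slide. Small intestine markers were lower with IIAEK in wild type (median -2.27, 6 of 9 lower, 5 called lower and 1 higher adjusted over the list alone, adjusted p = 0.0057, and 0.578 with an estimated correlation), including Vil1 at -2.27 (SE 0.60). This call was lost without wild-type vehicle 1 (adjusted p = 0.12, from 0.000387 over the left-out arrays), on slide 2 alone and with probes above background on all 12 arrays (0.300). Muc2 had a fitted change of -3.19 (SE 0.78), of which the size was not measured, as it was not above background on wild-type IIAEK 1 and 3. On slide 1, with 1 array per group, the list medians were 0.02 for matrix, -0.66 for NF-kappaB, -0.46 for immediate early, -0.24 for macrophage, -0.01 for fatty acid synthesis, -0.36 for PPARalpha, 0.34 for cholesterol synthesis, 0.26 for CAR and PXR and -0.16 for male-biased genes. On slide 2 they were -1.85, -1.35, -1.35, -0.85, 1.31, 0.90, 0.72, 0.64 and 1.61 in the same order. With the slide as a block 16 lists and 0 genes were called, and the block cannot move the fitted changes, as each slide holds all groups in equal shares. Tagln was called in 9 of 26 alternatives. Without wild-type vehicle 1 limma called 3911 genes (1715 higher, 2196 lower), Tagln among them, and without knockout vehicle 2 it called 2, Tagln included. Leaving out any other array ended the call of Tagln. Unadjusted, 3316 genes had p under 0.05 against 1320 by chance. Here and below, 1320 is the average count without any effect. As genes are correlated, a count can lie far from it without an effect, and these counts were not permuted. Camera called 17 of 33 lists and fry 0, and without the 4 vehicle arrays that stood apart 5 of the 17 were called, 1 of them (male-biased) in the opposite direction.

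**Figure D2:**
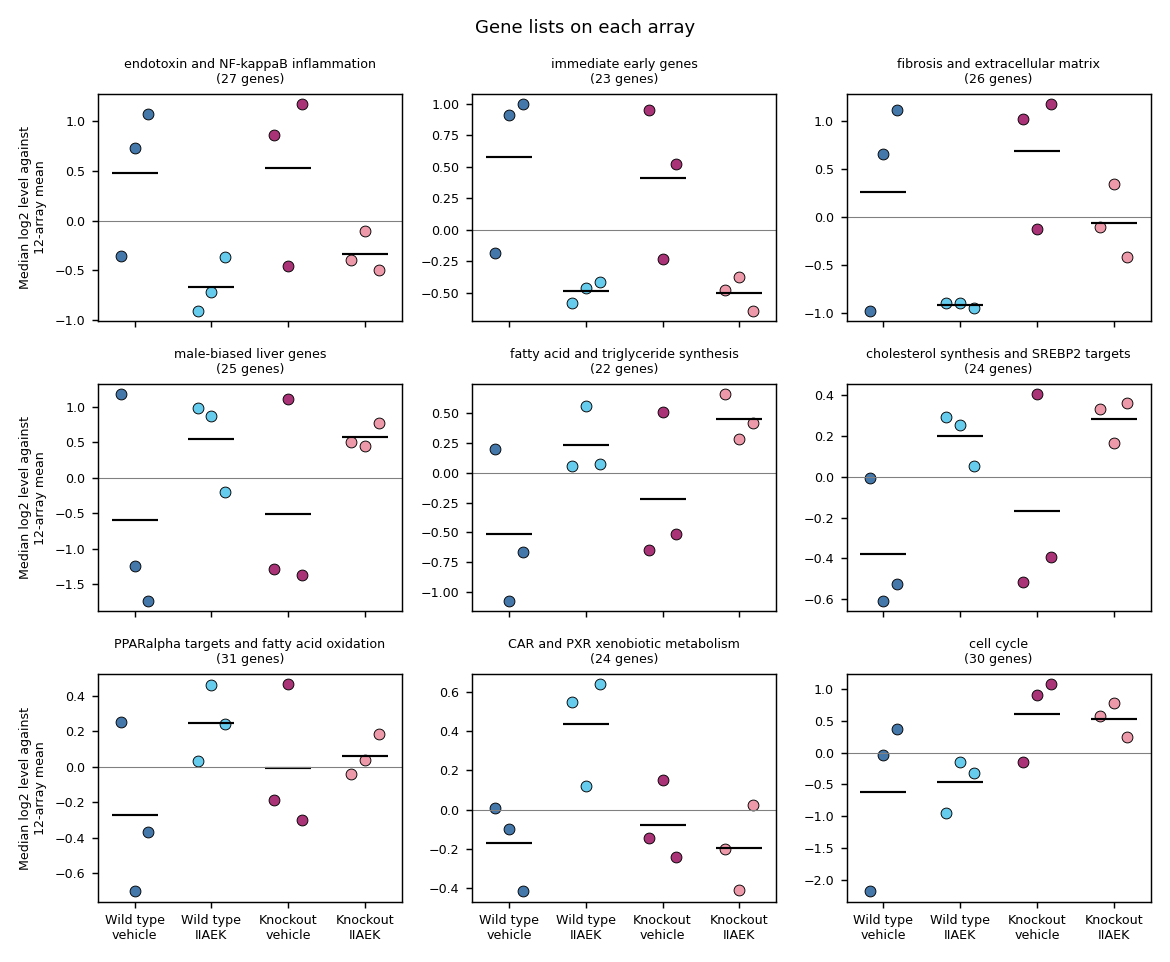
Median log2 level of 9 gene lists on each of the 12 arrays, relative to the mean of all 12 arrays (vertical axis), by group (horizontal axis), with a bar at the mean of 3 arrays. In both vehicle groups wild-type vehicle 1 and knockout vehicle 2 lie near the IIAEK arrays for most lists: the male-biased list is at 1.18 and 1.11 on these arrays and between -1.74 and -1.24 on the other 4 vehicle arrays.

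In knockout liver the IIAEK effect addresses what the peptide does without Akp3. No gene passed in limma. The genes with the smallest p and higher values were Extl1, a heparan sulfate glycosyltransferase (log2 change 1.36, SE 0.25), the aquaporin Aqp8 (1.48, SE 0.28), the metalloprotease Tll1 (0.82) and Upk3b (at least 1.87-fold higher). Lower values were those of Gadd45b (-1.61, SE 0.31), Igfbp2, a binding protein of insulin-like growth factors (-1.10, SE 0.21), Med12l (fitted -1.02) and Ttyh1 (at least 2.97-fold lower, above background on 0 of 3 IIAEK arrays). Med12l was not above background on all 12 arrays and ran from -1.24 to -0.10 over the alternatives. Adjusted p was 0.528 for Ttyh1 and 0.656 for the others.

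Early response and inflammation genes had the smallest p among the lists that fell in knockout liver. The calls of immediate early (adjusted p = 0.0618), NF-kappaB (0.410), matrix (0.0866) and cholangiocyte genes (0.834) were lost without the 4 vehicle arrays that stood apart, and that of red blood cell markers stayed (0.00828). Immediate early genes had a median of -0.86 with 21 of 23 lower and 1 called adjusted over the list alone (camera adjusted p = 2.18e-11), with Gadd45g at -1.04 (SE 0.23) and Egr1 at -1.91 (SE 0.63). In the NF-kappaB list 23 of 27 were lower (median -0.91, 1 called adjusted over the list alone, adjusted p = 2.24e-08), including the cytokines Il6 (at least 1.26-fold lower) and Il1a (-1.09, SE 0.38). The matrix list fell with 25 of 26 lower (median -0.74, 0 called adjusted over the list alone and 2 at an unadjusted p under 0.05, adjusted p = 7.72e-06), with Postn at -1.04 (SE 0.38) and Tgfb2 at -1.48 (SE 0.62). Red blood cell markers fell too, with 8 of 9 lower (median -1.60, 0 called adjusted over the list alone and 5 at an unadjusted p under 0.05, adjusted p = 4.34e-05), including the globins Hba-a1 (-1.32, SE 0.46) and Hba-a2 (-1.29, SE 0.45). Of the cholangiocyte markers 10 of 11 were lower (median -0.71, 0 called adjusted over the list alone and 2 at an unadjusted p under 0.05, adjusted p = 0.000835), with the chloride channel gene Cftr at -1.81 (SE 0.66) and Cldn7 at -0.71. For all 5 lists the adjusted p was 0.609 with an estimated correlation.

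Lipid synthesis and male-biased genes rose as sets in knockout liver. Both lipid lists lost their call without the 4 vehicle arrays that stood apart (adjusted p = 0.410 for fatty acid and 0.175 for cholesterol synthesis), and male-biased genes were then called in the opposite direction (0.0480). Fatty acid and triglyceride synthesis genes were higher for 21 of 22 (median 0.64, 0 called adjusted over the list alone and 6 at an unadjusted p under 0.05, adjusted p = 1.3e-05), with Aacs at 1.70 (SE 0.50) and Thrsp, a regulator of lipogenesis, at 2.38 (SE 0.93). Cholesterol synthesis genes were higher for 19 of 24 (median 0.47, adjusted p = 0.00662), with 1 called adjusted over the list alone, and with Sc5d, an enzyme late in the pathway, at 0.67 (SE 0.22). Both had an adjusted p of 0.609 with an estimated correlation. Male-biased genes were higher for 24 of 25 (median 1.14, 0 called adjusted over the list alone and 1 at an unadjusted p under 0.05, adjusted p = 8.65e-05, and 0.645 with an estimated correlation), with Hsd3b5 at 4.04 (SE 2.30) and Selenbp2 at 0.43. Cyp7a1 stood at -0.18 (SE 1.27) and turned to 1.74 on slide 2, Cyp8b1 at 3.48 (SE 1.97), Abca1 at -0.36, Abcg5 at 0.28 and Abcg8 at 0.70, and none of them passed (smallest unadjusted p among these and Alpl 0.00434 in limma, for Alpl).

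The knockout result of 0 genes came with 1706 genes at an unadjusted p under 0.05 against 1320 by chance. With the slide as a block the count was 0, on slide 2 alone 1, and with array weights 871 (508 higher, 363 lower). It was 6 without wild-type vehicle 1 and 1 without knockout vehicle 2. List medians on slide 1 and slide 2 were -1.58 and -0.55 for immediate early, -1.30 and -0.72 for NF-kappaB, -1.10 and -0.51 for matrix, -1.90 and -1.41 for red blood cell, -0.85 and -0.61 for cholangiocyte, 1.41 and 0.31 for fatty acid synthesis, 0.82 and 0.16 for cholesterol synthesis and 1.83 and 0.74 for male-biased genes. Camera called 13 of 33 lists (12 with the slide as a block) and fry 0. Without the 4 vehicle arrays that stood apart 3 of the 13 were called, 1 of them (male-biased) in the opposite direction, and the medians of the wild-type and knockout vehicle groups rest on these arrays.

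**Figure D3:**
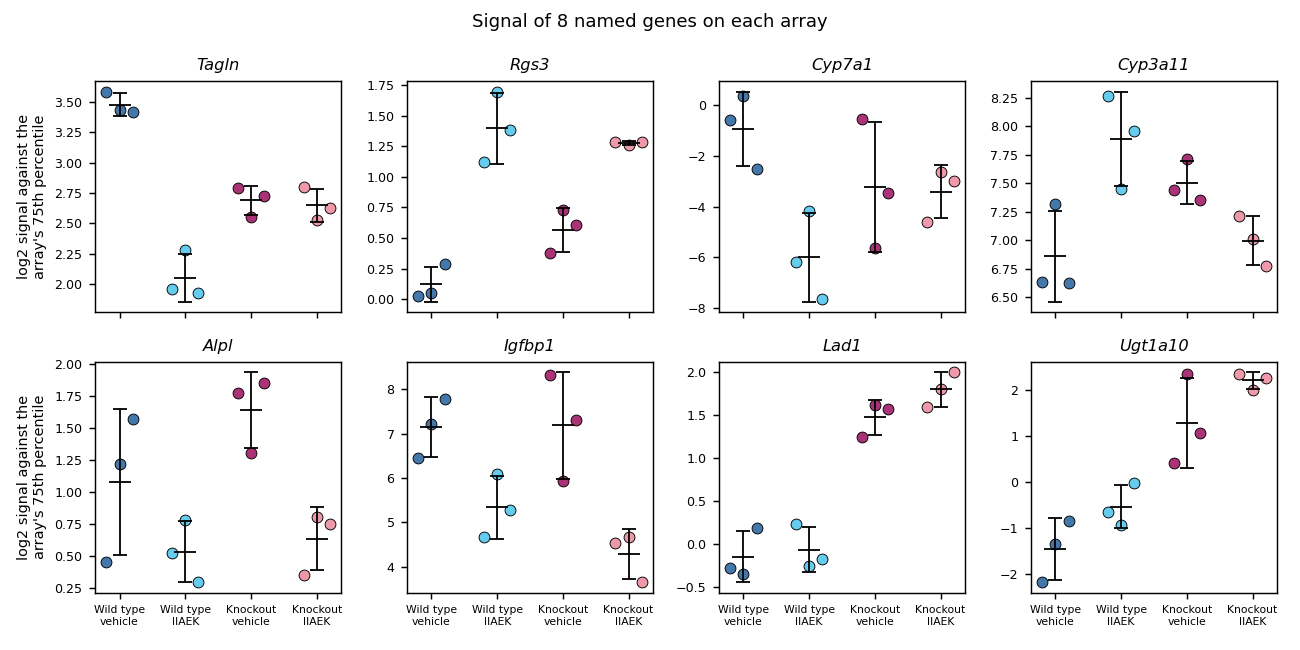
Log2 signal relative to the array's 75th percentile (vertical axis) of 8 named genes on each array by group (horizontal axis), with mean and SD of 3 arrays. Tagln is lower in wild-type IIAEK (2.05 ± 0.20) than in wild-type vehicle (3.48 ± 0.09), and Lad1 is higher on the 6 knockout arrays (1.24 to 2.0) than on the 6 wild-type arrays (-0.35 to 0.23).

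Whether the response depends on Akp3 was tested as the difference between both IIAEK effects, knockout minus wild type. The list of CAR and PXR drug-metabolizing genes had a lower response in knockout, with 22 of 24 members lower (median difference -0.94, camera adjusted p = 2.28e-09), and this was the 1 list whose call held with an estimated correlation (adjusted p = 0.0242). That value is adjusted over the 33 lists of this comparison only, and it was the 1 such pass in all 6 comparisons. Whether it would pass when adjusted over all 6 was not tested. Adjusted over the list alone 1 member was called. Cyp3a11 stood at a difference of -1.54 (SE 0.35) and Ces2a at -1.61 (SE 0.52). PPARalpha targets and fatty acid oxidation genes were lower for 28 of 31 (median -0.48, 0 called adjusted over the list alone and 5 at an unadjusted p under 0.05, adjusted p = 1.3e-11, and 0.374 with an estimated correlation), with the peroxisomal enzyme Ehhadh at -1.68 (SE 0.56) and Pdk4, a brake on glucose oxidation, at -1.98 (SE 0.70). Red blood cell markers were lower for 8 of 9 (median -1.47, 0 called adjusted over the list alone and 0 at an unadjusted p under 0.05, adjusted p = 9.51e-07, and 0.374 with an estimated correlation), with -1.41 for Hba-a1 and -1.40 for Hba-a2.

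The difference was above 0 for matrix genes and small intestine markers. Matrix genes fell with IIAEK in both genotypes, less so in knockout (median -0.74) than in wild type (-1.24). The median of small intestine markers was -2.27 in wild type and 0.20 in knockout. The matrix list had 25 of 26 members higher (median 0.53, adjusted p = 0.000623, and 0.831 with an estimated correlation) with 1 called adjusted over the list alone, Tagln at 1.39 (SE 0.21). Another member, Mmp13, stood at 1.39, with -1.68 on slide 1 and 2.93 on slide 2. This list's call was lost without wild-type vehicle 3, knockout vehicle 2 or knockout IIAEK 2, with adjusted p from 7.97e-12 to 0.954 over the left-out arrays, and without the 4 vehicle arrays that stood apart (0.234). Small intestine markers were higher for 8 of 9 (median 1.54, 0 called adjusted over the list alone and 2 at an unadjusted p under 0.05, adjusted p = 0.000279, and 0.333 with an estimated correlation). Their call was lost without the 2 wild-type vehicle arrays with pancreas or intestine transcripts (adjusted p = 0.161), on slide 2 alone and with probes above background on all 12 arrays. Muc2 is given no difference here, as it was above background on 0 of 3 knockout vehicle arrays, and the median level of these markers was 0.90, 2.60 and 0.47 on wild-type vehicle 1, 2 and 3. On slide 1 and slide 2 the median differences were -0.26 and -0.76 for CAR and PXR, 0.36 and -0.90 for PPARalpha, -2.96 and -0.82 for red blood cell, -1.28 and 1.31 for matrix and 1.25 and 1.67 for small intestine, so the PPARalpha and matrix differences turned on slide 1.

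No single gene passed the interaction test in limma (smallest adjusted p = 0.489). The genes with the smallest p were Gadd45g (-2.36, SE 0.33, adjusted p = 0.489), Tagln (1.39, adjusted p = 0.514), Lncbate1 (1.59), the mucin-like Fcgbp (fitted 3.08), Zmynd10 (1.42), Cyp3a11, Med12l (fitted -1.18) and the aquaporin Aqp3 (given no size, as it was below background in 2 of the 4 groups), the others with adjusted p = 1. Fcgbp and Med12l were not above background on all 12 arrays. Over the alternatives their fitted differences ran from 1.29 to 3.55 and from -1.31 to -0.21. Cyp7a1 had a fitted difference of 4.91 (SE 1.79, unadjusted p = 0.0197, adjusted p = 1), of which the size was not measured, as 2 of 3 wild-type IIAEK arrays were not above background. At an unadjusted p under 0.05 there were 426 genes, fewer than the 1320 of chance. With the slide as a block 0 genes and 10 lists were called, on slide 2 alone 0 genes and 14 lists, and 1 gene without knockout vehicle 2. Camera called 9 of 33 lists (3 higher, 6 lower), quantile normalization changed this split to 6 and 4, and fry called 0. Without wild-type vehicle 1 the number was 19 and without knockout vehicle 1 it was 15.

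The IIAEK effects of both genotypes, which share no array, were compared across the genes. Pearson r between the log2 changes of wild type and knockout was 0.749 and Spearman rho 0.700 over 26399 genes, and 77.2% of the genes had the same sign. An exact permutation of the labels within each genotype, two-sided, gave p = 0.14 (100 relabellings), and genes are not independent replicates. On slide 2 alone r was 0.675 (exact permutation p = 0.222, 9 relabellings). Leaving out knockout vehicle 2 gave r = 0.810 with an exact permutation p = 0.04, the 1 left-out array that took p below 0.05. In each genotype 2 of the 3 vehicle arrays were among the 4 that stood apart, and without these 4 r was -0.0257. These 4 were picked after the data had been seen, as the arrays farthest from the IIAEK arrays on the first component. Leaving them out removes much of the difference between vehicle and IIAEK by construction. The fall of r therefore cannot tell an effect of IIAEK from a difference among the vehicle mice.

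Averaged over both genotypes, the IIAEK effect compares 6 mice with 6, and camera called inflammation, early response, bile duct and lipid synthesis genes as sets. Of these only the immediate early call held without the 4 vehicle arrays that stood apart (adjusted p = 0.00107), while those of NF-kappaB (0.397), cholangiocyte (0.701), fatty acid synthesis (0.769) and cholesterol synthesis genes (0.788) were lost. In the NF-kappaB list 24 of 27 were lower (median -0.98, camera adjusted p = 5.19e-10), and 19 were called adjusted over the list alone, with Cd14, the endotoxin co-receptor, at -1.96 (SE 0.49) and Il1a at -1.06 (SE 0.27). Of the immediate early genes 19 of 23 were lower (median -0.93, adjusted p = 3.57e-09) and 15 were called adjusted over the list alone, with Egr1 at -2.17 (SE 0.45) and Klf4 at -1.02 (SE 0.22). Among cholangiocyte markers 6 of 11 were called lower adjusted over the list alone (median -0.81, adjusted p = 0.00106), with Cftr at -1.77 (SE 0.47) and Cldn7 at -0.81 (SE 0.22). Fatty acid synthesis genes were higher for 22 of 22 (median 0.76, adjusted p = 6.5e-07), and 7 were called adjusted over the list alone, with Aacs at 1.48 (SE 0.35) and Pnpla3 at 1.10 (SE 0.29; -0.32 at its other probe). Cholesterol synthesis genes were higher for 20 of 24 (median 0.56, adjusted p = 0.000852), and adjusted over the list alone 5 were called higher and 1 lower, with Insig1 at 0.97 (SE 0.22) and Hmgcs1 at 1.30 (SE 0.32). Each of these 5 lists had an adjusted p of 0.614 with an estimated correlation. The 5 lists kept their direction on both slides, with medians on slide 1 and slide 2 of -0.94 and -1.07, -1.01 and -0.94, -0.46 and -1.01, 0.78 and 0.81, and 0.49 and 0.50.

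No gene passed over all genes in the averaged IIAEK comparison (smallest adjusted p = 0.145 in limma). Rgs3 came closest, with a log2 level of 1.34 ± 0.20 in 6 IIAEK mice and 0.35 ± 0.28 in 6 vehicle mice (change 0.99, SE 0.12, adjusted p = 0.145). Its 4 probes gave changes from 0.28 to 0.99. The next genes were Aqp8 (1.33, SE 0.20), Cdan1 (0.75), Ankrd9 (0.74), Tagln (-0.73, SE 0.10), the metalloprotease Pappa (at least 2.32-fold lower), Igfbp1, a liver protein that insulin represses (-2.35, SE 0.42), and Mrgpra4 (at least 1.76-fold lower, above background on 0 of 3 wild-type IIAEK arrays), all with adjusted p = 0.18. Unadjusted, 6030 genes had p under 0.05 (3119 higher, 2911 lower) against an average of 1320 by chance. Correlated genes can exceed that average without an effect, and the count was not permuted. The count of 0 was the same with the slide as a block and became 4 on slide 2 alone, 7824 with array weights, 6508 without wild-type vehicle 1 and 2523 without knockout vehicle 2. Camera called 12 of 33 lists (4 higher, 8 lower; 3 and 10 with quantile normalization) and fry 0, and an exact permutation of per-array list means gave a smallest adjusted p of 0.165, for immediate early genes (unadjusted 0.005, the smallest that 400 relabellings can give). Without the 4 vehicle arrays that stood apart 3 of the 12 lists were called, 2 of them (male-biased and hepatocyte) in the opposite direction.

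Between genotypes in vehicle mice, the comparison asks what the loss of Akp3 does to the liver without the peptide. A probe named by its mm9 position on chromosome 1, 74084292 to 74138492 (chr1:74084292-74138492_R), fell from -0.87 ± 0.17 in wild type to -3.16 ± 0.10 in knockout (SD, n = 3 each, log2 change -2.29, SE 0.18, limma adjusted p = 0.00224). It was the 1 gene called, was lower in 3 of 3 knockout mice, and was called in 22 of 26 alternatives (adjusted p from 0.00129 to 0.218). Lad1, a protein of basement membrane anchoring filaments, stood at 1.62 (SE 0.20, adjusted p = 0.102) and Ugt1a10, a glucuronosyltransferase, at 2.73 (SE 0.47, adjusted p = 0.54). Further genes that did not pass were Aqp3 (at least 1.66-fold higher), Cox6b2 (1.38), Tagln (-0.79), Utp14b (-1.33) and Pcf11 (-0.78). With normexp Aqp3 turned to -0.02.

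Cell cycle genes were higher in knockout liver as a set. Of 30 members 24 were higher (median 1.23, camera adjusted p = 8e-11, and 0.8 with an estimated correlation), 0 were called adjusted over the list alone and 14 had an unadjusted p under 0.05. Plk1, a mitotic kinase, stood at 2.21 (SE 0.64) and Cdc20, which drives exit from mitosis, at 2.56 (SE 0.75). Wild-type vehicle 1, the array with pancreas transcripts, had the lowest level of this list (-2.18 against the 12-array mean), and the adjusted p ran from 5.84e-18 to 0.0349 over the left-out arrays, highest without it. Without both wild-type vehicle arrays with transcripts of another organ it was 0.294. PPARalpha targets were higher for 25 of 31 (median 0.32, 0 called adjusted over the list alone and 2 at an unadjusted p under 0.05, adjusted p = 0.000529, and 0.8 with an estimated correlation), with the lipid droplet gene Cidec at 1.69 and Acot2 at 0.90. Cidec stood at 3.82 on slide 1 and 0.62 on slide 2, and from 0.88 without wild-type vehicle 1 to 2.34 without wild-type vehicle 3. That call was lost without wild-type vehicle 2 or knockout vehicle 2 (adjusted p from 9.33e-08 to 0.144 over the left-out arrays) and without the 4 vehicle arrays that stood apart (0.255).

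Pancreas and small intestine markers were lower in knockout vehicle livers than in wild-type ones. For pancreas 12 of 12 were lower (median -0.99, 0 called adjusted over the list alone and 1 at an unadjusted p under 0.05, adjusted p = 0.00344, and 0.8 with an estimated correlation), with the colipase gene Clps at -1.12. Reg1 had a fitted change of -3.11 (SE 1.06), of which the size was not measured, as it was not above background on knockout vehicle 1 and 2. Over the left-out arrays Reg1 ran from -4.50 to -1.95 and Clps from -1.86 to -0.23. Without wild-type vehicle 1 the direction of this list turned (adjusted p = 0.942, from 1.81e-05 over the left-out arrays), as it did on slide 2 alone (0.465). Small intestine markers were lower for 6 of 9 (median -0.87, 4 called lower adjusted over the list alone, adjusted p = 0.0136, and 0.8 with an estimated correlation), with the mucin Muc2 at least 7.46-fold lower over all 12 arrays and sucrase-isomaltase (Sis) at a fitted -3.67 (SE 1.01). Sis was not above background on knockout vehicle 1. Over the left-out arrays the fitted changes ran from -3.58 to -2.43 for Muc2 and from -4.83 to -2.47 for Sis. Both were smallest without wild-type vehicle 2, the array highest in intestine transcripts. The call of the small intestine list was lost without wild-type vehicle 1 or knockout vehicle 1 (adjusted p from 0.00308 to 0.164), on slide 2 alone, and with probes above background on all 12 arrays (0.723). On slide 1 and slide 2 the median changes were 2.09 and 0.79 for cell cycle, -0.51 and 0.62 for PPARalpha, -3.20 and 0.12 for pancreas and -1.21 and -1.09 for small intestine.

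In this comparison 1815 genes had an unadjusted p under 0.05 against 1320 by chance. With the slide as a block the called probe was the same 1, and on slide 2 alone 1 other gene was called. Without wild-type vehicle 3 or knockout vehicle 2 the count was 2, the probe included. Normexp gave 2 genes, 1 higher and 1 lower, and shifted the median of all genes from -0.07 to -0.12, so small changes between genotypes are relative to that shift. Camera called 12 of 33 lists (9 higher, 3 lower; 11 and 1 with normexp) and fry 0, and the number was 7 without wild-type vehicle 1. Without the 4 vehicle arrays that stood apart 60 genes (52 higher, 8 lower) were called, without the chromosome 1 probe, but this sets 1 knockout array against 1 wild-type array, the one with pancreas transcripts.

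Averaged over both treatments, 6 knockout mice differed from 6 wild-type mice in 5 genes. Lad1 rose from -0.11 ± 0.25 to 1.64 ± 0.25 (SD, log2 change 1.74, SE 0.14, limma adjusted p = 0.00176), with the same change at its other probe (1.74). Ugt1a10 rose 6.68-fold, from -1.0 ± 0.72 to 1.74 ± 0.81 (change 2.74, SE 0.33, adjusted p = 0.0363). The chromosome 1 probe fell from -1.06 ± 0.30 to -3.02 ± 0.20 (change -1.96, SE 0.13, adjusted p = 0.000309). Utp14b, a gene of ribosomal RNA processing, fell at least 2.75-fold (adjusted p = 0.0363, above background on 0 of 3 knockout IIAEK arrays). The transcript ENSMUST00000187871, for which no symbol was found, fell too (change -1.22, SE 0.15, adjusted p = 0.0379). With the slide as a block Utp14b and ENSMUST00000187871 lost their call while Lad1, Ugt1a10 and the chromosome 1 probe kept it, and on slide 2 alone 0 of the 5 were called. For each of the 5, the 6 knockout arrays lay all on the same side of the 6 wild-type arrays. Dlgap5, a mitotic spindle gene (at least 1.34-fold higher, adjusted p = 0.0517) and Mob1a (-0.66, adjusted p = 0.164) did not pass.

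Cell cycle and matrix genes were higher as sets in knockout mice over both treatments. In the cell cycle list 26 of 30 were higher (median 1.10, camera adjusted p = 2.24e-11, and 0.882 with an estimated correlation), and 14 were called adjusted over the list alone, with Cdc20 at 2.35 (SE 0.53) and Plk1 at 1.94 (SE 0.45). Matrix genes were higher for 23 of 26 (median 0.62, 0 called adjusted over the list alone and 7 at an unadjusted p under 0.05, adjusted p = 4.33e-06, and 0.882 with an estimated correlation), with Mmp2 at 1.42 (SE 0.41) and the collagen Col4a2 at 0.82 (SE 0.27). On slide 1 and slide 2 the medians were 1.87 and 0.76 for cell cycle and 1.33 and 0.26 for matrix. Wild-type vehicle 1 was at -2.18 for cell cycle and -0.98 for matrix, and without it and wild-type vehicle 2 the adjusted p was 5.83e-07 for cell cycle and 0.125 for matrix, whose call was also lost on slide 2 alone.

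The chromosome 1 probe was called in 24 of 25 alternatives (adjusted p from 0.000167 to 0.104), Lad1 in 23 of 25 (0.000312 to 0.104), Ugt1a10 in 14 of 25 (0.00904 to 0.421), Utp14b in 10 of 24 (0.00851 to 0.197) and ENSMUST00000187871 in 10 of 25 (0.0131 to 0.269). On slide 2 alone the log2 changes were 2.71 for Ugt1a10, 1.89 for Lad1, -1.95 for the chromosome 1 probe and -1.31 for ENSMUST00000187871, and on slide 1 they were 2.79, 1.44, -2.0 and -1.02. Utp14b was lower on both slides. The count was 8 without wild-type vehicle 1 and 9 without wild-type vehicle 3, and fell to 2 without knockout vehicle 3, wild-type IIAEK 1 or 2, or any of the knockout IIAEK arrays, and to 3 without knockout vehicle 2 or wild-type IIAEK 3. Without the 4 vehicle arrays that stood apart it was 129, 4 of the 5 included. Unadjusted, 4350 genes had p under 0.05. Camera called 11 of 33 lists (9 higher, 2 lower; 10 and 0 with normexp) and fry 0, with 6 lists without wild-type vehicle 2 or knockout vehicle 2 and 7 without wild-type vehicle 3.

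All 3 called genes with a symbol and a known place, Lad1, Ugt1a10 and Utp14b, lay on the chromosome of Akp3, and the called probe with a position was on chromosome 1 as well. Counted in genes along the chromosome from Akp3, Ugt1a10 stood at 32, Utp14b at -139 and Lad1 at 663. Among the 100 neighbouring genes on either side of Akp3, 1 of 54 tested genes was called, against 2 of 15273 elsewhere (Fisher's exact test, two-sided, p = 0.0105). At an unadjusted p under 0.01 it was 6 of 54 against 561 of 15273 (Fisher's exact p = 0.0143). With 50 neighbours the exact p was 0.00606 and 0.00521, and with 200 neighbours it was 0.000203 and 0.000851. Of the 50 genes with the smallest p, 16 had a symbol and 4 lay on this chromosome, which holds 5.66% of the tested symbols.

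**Figure D4:**
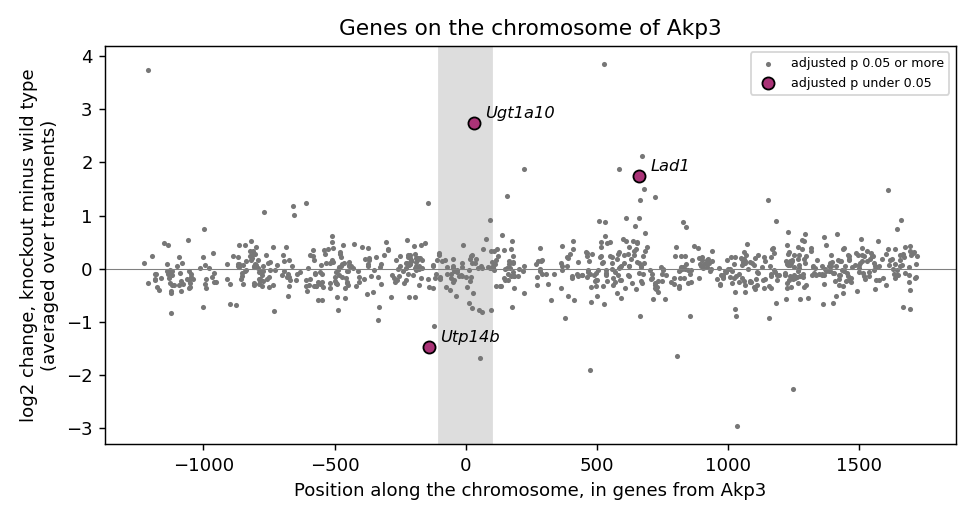
Log2 change between knockout and wild type, averaged over treatments (vertical axis), of the tested genes on the chromosome of Akp3 in their order, counted in genes from Akp3 (horizontal axis), with a grey band over 100 neighbours on either side and large points for the called genes. Ugt1a10 (2.74) lies in the band at 32 genes, Utp14b (plotted at -1.47, a fitted value and not a bound) at -139 and Lad1 (1.74) at 663.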

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

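The interaction test, the lists and the 100 neighbours of Akp3 were planned, and the tests of explanations below, the settings without 2 or 4 vehicle arrays, the count of probes named by position and the count over the whole chromosome were chosen after the results had been seen. What brought the following results here is a difference between groups: the response to IIAEK in knockout minus that in wild type passed camera for 9 lists. With groups of 3 arrays, single arrays were not tested for lying far from the others.

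Of the 9 lists, CAR and PXR drug metabolism had a median difference of -0.94, PPARalpha targets of -0.48 and red blood cell markers of -1.47, as given in the report, and matrix genes (0.53) and small intestine markers (1.54) had differences above 0. The other 4 were heat shock proteins, which fold other proteins (median -0.26, 17 of 18 lower, adjusted p = 0.000277, and adjusted p = 0.374 with an estimated correlation), NRF2 antioxidant genes (-0.093, 13 of 21 lower, adjusted p = 0.0281, and 0.374 with an estimated correlation), female-biased liver genes (-0.38, 11 of 18 lower, adjusted p = 0.0281, and 0.831 with an estimated correlation) and T and NK cell markers (0.47, 13 of 14 higher, adjusted p = 0.0281, and 0.831 with an estimated correlation). The heat shock difference turned on slide 1 (median 0.10, and -0.34 on slide 2), and its call was also lost in another of the settings. The last 3 of these lists rest on single arrays. The NRF2 call was lost without wild-type vehicle 1, wild-type IIAEK 1, knockout vehicle 3 or knockout IIAEK 3 (adjusted p from 0.00198 to 0.420 over the left-out arrays). The female-biased call was lost without wild-type vehicle 1, knockout vehicle 1 or 3 or knockout IIAEK 3, and turned without wild-type IIAEK 3 (0.000444 to 0.855). The T and NK call was lost without wild-type vehicle 2 or 3, wild-type IIAEK 1 or 2, knockout vehicle 2 or knockout IIAEK 2 (6.31e-05 to 0.768).

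The 4 vehicle arrays that stood apart (wild type 2 and 3, knockout 1 and 3) had high inflammation and early response genes and low lipid synthesis and male-biased genes, and without them 5 of 17 lists were called for IIAEK in wild type, 3 of 13 in knockout and 3 of 12 averaged, with male-biased genes in the opposite direction in all 3. Signal strength stays open: 2 other arrays had a 75th percentile within the range of these 4, but the median signal of the 4 (49.9 to 52.9) lay above that of the other 8 (at most 47.6). Their share of probes well above background was higher too (62.6% to 63.6%, against at most 62.1%). The slopes of their spike-in controls were 0.916 to 0.928. Wild-type vehicle 1 lay within that range (0.925), and the remaining arrays were at 0.941 or more. A lower share of hepatocytes alone would raise the markers of other cell types alike. Macrophage markers exceeded endothelial ones by 0.63 to 1.2 log2, at least 3.27 standard errors over marker genes, which are not independent replicates. This argues against a lower share as the only cause, for these cell types. A lower share beside other changes stays open. A swap of vehicle and IIAEK labels would leave an IIAEK array on the far side of the component, where 0 of the 6 lay. This holds only if vehicle mice as such lie there, and it reads the positions that defined the pattern. A single wrong label stays open. IIAEK itself, the biological explanation that the design names, stays open for these 4 but would not set wild-type vehicle 1 and knockout vehicle 2 beside the IIAEK arrays, and a difference among the vehicle mice in feeding or time of sampling may be involved, which was not tested.

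Pancreas transcripts, highest in wild-type vehicle 1, and small intestine transcripts, highest in wild-type vehicle 2 and raised on the other wild-type vehicle arrays too, may come from RNA of these organs in the piece of tissue or in the handling. Of the markers dimmer than the array's 75th percentile on the median array, 90% of the pancreas ones (9 of 10) were highest in wild-type vehicle 1 and 83.3% of the small intestine ones (5 of 6) in wild-type vehicle 2. Counting the markers that are bright in these livers too (Amy2a5, Cela1, Anpep, Apoa4 and Fabp2), which was the count first tried, it was 9 of 12 and 5 of 9. Against the 12-array mean, with arrays below background set to the lowest signal above it, Try5 shifted by at least 5.50, Try4 by at least 5.36 and Sis by at least 5.16, and Defa24 by 5.19, while the brightest pancreas probes were at 0.46 (Cela1), 0.19 (Amy2a5) and 2.90 (Cela2a) and the other bright intestine probes at 0.89 (Apoa4), -0.0054 (Fabp2) and -0.91 (Anpep), though brightness does not rank transcripts. Noise of dim probes was argued against for both lists, whose medians of 2.72 and 2.60 stood at percentile 100 and percentile 100 of 10000 random lists of like level (-0.65 to 0.68 and -0.81 to 0.93), and no biological explanation was tested.

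The 3 genes with a symbol called between genotypes lay on the chromosome of Akp3 (3 of 867 tested genes there, 0 of 14460 elsewhere, an observation and not a test). A candidate explanation is sequence of the strain that supplied the targeted cells, kept around the locus by linkage, which would change expression or probe binding there. The planned test fits that (100 neighbours, Fisher's exact p = 0.0105), and it rests on 1 called gene, Ugt1a10. How far such a stretch reaches stays open, as at an unadjusted p under 0.01 the whole chromosome had 44 of 867 genes against 523 of 14460 elsewhere (Fisher's exact p = 0.0327), while probes named by their position on chromosome 1 had no excess (4 of 142 against 66 of 1826, exact p = 0.815). Loss of Akp3 itself, a biological explanation that the design names, stays open, as no strain information was at hand.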

How the results depend on the processing

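The settings without the 2 wild-type vehicle arrays with pancreas or intestine transcripts, without the 4 vehicle arrays that stood apart, and without an interaction in the model were added after the data had been seen. Of the values for 122 gene changes, 1356 kept their direction and side of the threshold when an array was left out (65 newly passed, 36 no longer passed, 7 reversed), and 1526 did under the other settings (66, 28 and 12). Where an array left a group with 1 or 2, limma assumed that it varies like the other groups. What signal over background limits is the number of genes tested, 26399 here, 45607 without a filter and 23572 with probes above background on all 12 arrays.

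The counts of genes called moved as follows, and the cause was not tested. In wild type (1 gene) it was 2 without a filter on dim probes, 0 with the slide as a block, 0 on only the slide with 2 arrays per group, 0 with only the groups compared, 0 with array weights, 0 without the 2 wild-type vehicle arrays and 0 to 3911 over the left-out arrays (3911 without wild-type vehicle 1). Without the 4 vehicle arrays 1 other gene was called. In knockout (0 genes) it was 1 without a filter on dim probes, 1 on slide 2, 1 with only the groups compared, 871 with array weights, 5 without the 2 wild-type vehicle arrays and 0 to 6 over the left-out arrays (6 without wild-type vehicle 1). Between genotypes in vehicle mice (1) it was 2 with normexp, 2 without a filter, 0 with only the groups compared, 0 without the 2 wild-type vehicle arrays, 60 without the 4 vehicle arrays and 1 to 2 over the left-out arrays. For the interaction (0) it was 1 without the 4 vehicle arrays and 0 to 1 over the left-out arrays. For IIAEK averaged (0) it was 1 without a filter, 4 on slide 2, 7824 with array weights (4218 higher, 3606 lower), 2175 without the 2 wild-type vehicle arrays (1100 higher, 1075 lower), 1 without the 4 vehicle arrays and 0 to 6508 over the left-out arrays (6508 without wild-type vehicle 1, 2523 without knockout vehicle 2). For genotype averaged (5) it was 8 without a filter, 3 with the slide as a block, 0 on slide 2, 10 with array weights, 1 without the 2 wild-type vehicle arrays, 129 without the 4 vehicle arrays (111 higher, 18 lower) and 2 to 9 over the left-out arrays. The additive model gave 0 genes for IIAEK (limma) and 6 for genotype.

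The replicate number as a block (replicate block) gave 0 genes in wild type, 0 in knockout, 1 between genotypes in vehicle mice, 0 for the interaction, 0 for IIAEK averaged and 2 for genotype averaged, with limma. The numbers do not pair the samples: 8 of 18 same-number pairs had deviations correlated above 0.1 (r from -0.55 to 0.65), with a median of 0.039 against 0.0067 for other pairs.

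The counts of lists called moved too. With an estimated correlation camera called 0 in wild type, 0 in knockout, 0 between genotypes in vehicle mice, 1 for the interaction, 0 for IIAEK averaged and 0 for genotype averaged, and fry called 0 in each of the 6. In wild type (17 lists) 11 were called without the 4 vehicle arrays and 13 to 18 over the left-out arrays. For the interaction (9) it was 14 on slide 2, 15 without the 2 wild-type vehicle arrays, 15 without the 4 vehicle arrays and 8 to 19 over the left-out arrays. For genotype averaged (11) it was 6 with quantile normalization, 7 without the 2 wild-type vehicle arrays and 6 to 10 over the left-out arrays, and between genotypes in vehicle mice (12) 7 to 14. In knockout (13) the left-out arrays gave 11 to 15 and for IIAEK averaged (12) 9 to 15. The correlation of both IIAEK effects across genes, r = 0.749, ran from 0.613 to 0.810 over the planned settings and was -0.0257 without the 4 vehicle arrays.

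Genes that reversed were, without the 4 vehicle arrays, in wild type Alpl (0.084), Abcg8 (-0.65), Nr1h4 (-0.066) and Keg1 (-0.0085), and in knockout Cyp7a1 (2.24) and Hsd3b5 (-1.23). On slide 2 they were Cyp8b1 in wild type (2.79) and Cyp7a1 in knockout (1.74), with array weights Cyp8b1 in wild type (1.23), without the 2 wild-type vehicle arrays Cyp8b1 in wild type (2.07) and Clps between genotypes (0.36), and with normexp Aqp3 between genotypes (-0.024). Over the left-out arrays the ranges that held 0 were, in wild type, Abcg5 -0.25 to 0.029, Abcg8 -0.058 to 0.84 and Cyp8b1 -1.86 to 2.0, and in knockout Cyp7a1 -1.40 to 1.15. The cause was not tested.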

Other observations

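The splits of the samples, the setting without the 2 wild-type vehicle arrays and the permutation of list means in this part were chosen after the results had been seen, while the lists and the other settings were planned. Several cell type lists not yet described fell with IIAEK in camera. Macrophage markers fell in knockout (median -0.68, 18 of 19 lower, adjusted p = 4.34e-05, and 0.609 with an estimated correlation) and averaged over genotypes (-0.68, 17 of 19, adjusted p = 8.39e-05, and 0.614 with an estimated correlation). Stellate cell markers fell averaged over genotypes (-0.24, 12 of 13, adjusted p = 0.00536, and 0.614 with an estimated correlation), in wild type (-0.30, 12 of 13, adjusted p = 0.00824, and 0.578 with an estimated correlation; lost without wild-type vehicle 3, at 0.145) and in knockout (-0.24, 10 of 13, adjusted p = 0.0135, and 0.609 with an estimated correlation; lost without knockout vehicle 3 or knockout IIAEK 3, up to 0.198). All these calls were lost without the 4 vehicle arrays that stood apart (adjusted p from 0.447 to 0.899).

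In wild type the calls of further cell type lists as lower rest on single arrays, and all had adjusted p from 0.578 to 0.735 with an estimated correlation. They were cholangiocyte (-0.93, 9 of 11, adjusted p = 0.0052, lost without vehicle 3, at 0.0537), MHC class II (-0.72, 7 of 7, adjusted p = 0.0132, lost without vehicle 3 or IIAEK 1, up to 0.145) and B and plasma cell markers (-0.61, 6 of 8, adjusted p = 0.0184, lost without vehicle 1 or 3, up to 0.0624). Neutrophil markers (-1.26, 6 of 8, adjusted p = 0.034) lost their call without vehicle 1, 2 or 3 or IIAEK 2 (up to 0.0940), and T and NK cell markers (-0.36, 12 of 14, adjusted p = 0.0446) without vehicle 1 or 3 or IIAEK 1 or 2 (up to 0.336). Pancreas markers (-0.87, 10 of 12, adjusted p = 0.034) turned without wild-type vehicle 1, the array with pancreas transcripts (adjusted p = 0.478), and lost their call without wild-type IIAEK 2 or 3 or knockout vehicle 2. In knockout hepatocyte markers were higher (0.26, 16 of 16, adjusted p = 0.0111, and 0.702 with an estimated correlation), lost without knockout vehicle 3 (0.260). Heat shock genes (-0.16, adjusted p = 0.0286, and 0.609 with an estimated correlation) lost their call without knockout vehicle 2 or knockout IIAEK 2 (up to 0.189), and female-biased genes (-0.32, adjusted p = 0.0439, and 0.638 with an estimated correlation) without wild-type vehicle 3, wild-type IIAEK 3, knockout vehicle 1 or 3, or knockout IIAEK 2 or 3 (up to 0.256).

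Averaged over genotypes, matrix genes fell with IIAEK (median -0.98, 25 of 26 lower, 6 called adjusted over the list alone, adjusted p = 5.19e-10, and 0.614 with an estimated correlation) and male-biased genes rose (1.01, 24 of 25 higher, adjusted p = 0.000131, and 0.786 with an estimated correlation). The matrix call was lost without the 4 vehicle arrays that stood apart (adjusted p = 0.482), where male-biased genes and hepatocyte markers were called in the opposite direction. Hepatocyte markers were higher (0.20, 15 of 16, adjusted p = 0.0254, and 0.786 with an estimated correlation), lost without wild-type vehicle 2 or 3 or knockout vehicle 3 (up to 0.114). B and plasma cell markers (-0.45, adjusted p = 0.039, and 0.614 with an estimated correlation) lost their call without wild-type vehicle 1 or 3, wild-type IIAEK 1, knockout vehicle 3 or knockout IIAEK 3 (up to 0.193). For red blood cell markers (-0.79, adjusted p = 0.0491, and 0.786 with an estimated correlation) the call was lost without 9 of the 12 arrays, the exceptions being wild-type vehicle 1, wild-type IIAEK 3 and knockout IIAEK 1 (up to 0.141).

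Between genotypes in vehicle mice endothelial markers were higher in knockout (0.26, adjusted p = 0.00304). That call was lost without the 4 vehicle arrays that stood apart (adjusted p = 0.718, and 0.000635 to 0.0348 over the left-out arrays), and the median was -0.11 on slide 1 and 0.42 on slide 2. The other lists called higher were each lost without single arrays. They were fatty acid synthesis (0.23, adjusted p = 0.00264, lost without wild-type vehicle 2 or knockout vehicle 2, up to 0.781), cholesterol synthesis (0.23, adjusted p = 0.00656, lost without wild-type vehicle 2 or 3 or knockout vehicle 2, up to 0.567) and heat shock (0.17, adjusted p = 0.0135, lost without wild-type vehicle 1 or knockout vehicle 1, up to 0.143). Matrix genes (0.47, adjusted p = 0.0135) lost their call without knockout vehicle 1 or 3 (up to 0.548) and turned without wild-type vehicle 1, as they did, called lower, without the 2 wild-type vehicle arrays with pancreas or intestine transcripts. Interferon response (0.11, adjusted p = 0.0472) was lost without wild-type vehicle 1 or 2, wild-type IIAEK 2 or any knockout vehicle array (up to 0.752). Stellate cell markers (0.25, adjusted p = 0.0491) turned without wild-type vehicle 1 (0.915) and were lost without wild-type IIAEK 2, knockout vehicle 1 or 3 or knockout IIAEK 1. Acute phase genes were lower (-0.29, adjusted p = 0.0135, lost without wild-type vehicle 1 or knockout vehicle 2, up to 0.369). All 8 lists had adjusted p of at least 0.8 with an estimated correlation. The medians on slide 1 and slide 2 were -0.83 and 0.89 for fatty acid synthesis, -0.63 and 0.55 for cholesterol synthesis and 2.11 and -0.31 for matrix genes.

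Averaged over treatments 9 further lists were called between genotypes, each lost without some arrays and each with adjusted p = 0.882 with an estimated correlation. Higher in knockout were fatty acid synthesis (0.18, adjusted p = 0.00969, lost without wild-type vehicle 2 or knockout vehicle 2, up to 0.299), stellate cell (0.22, lost without wild-type vehicle 1 or wild-type IIAEK 2, up to 0.281) and B and plasma cell markers (0.56, lost without wild-type vehicle 1 or knockout vehicle 3, up to 0.115). Circadian clock genes (0.18) were lost without wild-type vehicle 3, knockout vehicle 2 or knockout IIAEK 3 (up to 0.119), cholesterol synthesis (0.07) without wild-type vehicle 2 or 3, wild-type IIAEK 3, knockout vehicle 2 or knockout IIAEK 1 (up to 0.369), and endothelial markers (0.14) without wild-type vehicle 2 or 3, wild-type IIAEK 1, knockout vehicle 2 or knockout IIAEK 1 (up to 0.0945). These 5 had adjusted p = 0.031. Interferon response (0.15, adjusted p = 0.0453) was lost without 8 of the 12 arrays, the exceptions being wild-type vehicle 3, wild-type IIAEK 3 and knockout IIAEK 1 and 3 (up to 0.468). Lower were pancreas markers (-0.72, adjusted p = 0.031), lost without wild-type vehicle 1, the array with pancreas transcripts (0.472), wild-type IIAEK 1, knockout vehicle 1 or 2 or knockout IIAEK 3, and red blood cell markers (-0.76, adjusted p = 0.044), lost without wild-type vehicle 2 or 3, wild-type IIAEK 3, knockout vehicle 2 or knockout IIAEK 2 or 3 (up to 0.213).

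Of the lists tested, 6 were called in none of the 6 comparisons by camera: AhR targets (smallest adjusted p = 0.69), bile acid synthesis and transport (0.164), cholesterol efflux and lipoproteins (0.243), gluconeogenesis (0.311), adipose markers (0.731) and the unfolded protein response (0.515). Their medians in wild type and knockout with IIAEK were 0.005 and 0.23, 0.25 and 0.21, 0.09 and 0.23, -0.03 and -0.09, 0.36 and 0.25, and 0.15 and 0.07 in the same order. Exact permutation of per-array list means left 0 of 33 lists past the threshold for the averaged comparisons (smallest adjusted p = 0.165 for IIAEK and 0.495 for genotype), and with 3 arrays against 3 the smallest p is 0.1. For the averaged comparisons the smallest p that this permutation can give is 0.005. A single list at that floor has an adjusted p of 0.165 over the 33 lists. Only several lists at or near the floor could have passed, so the count of 0 decides little.

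Other splits of the arrays were fitted in the same way. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05: as many genes were called in 2 of 10 for IIAEK in wild type (real 1, highest other 1) and 5 of 10 between genotypes in vehicle mice (1 and 90). For genotype averaged, 2 of 100 drawn splits of 200, the real one included, gave as many (real 5, highest other 164). This share is small, but as another split gave 164 genes, it does not exclude chance for the count of 5. That count moved with the settings, to 0 on slide 2 alone. Where the real count is 0 every split gives as many, so the count tests nothing for IIAEK in knockout (10 of 10, highest other 0), the interaction (100 of 100, highest other 216) and IIAEK averaged (100 of 100, highest other 0). The splits with 90 genes (knockout vehicle 2 and wild-type vehicle 3 trading places), 164 genes (these 2 and 2 IIAEK arrays, knockout 3 and wild type 3) and 216 genes point to a structure of the samples, since 164 is many times the real 5. In the split with 90 genes, 3 of the 4 vehicle arrays that stood apart were in 1 group.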
